A study of Mus musculus with 17 samples.

How the data were processed

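Total kidney RNA of 17 male BALB/c mice was hybridised to NimbleGen expression arrays of 12 arrays per slide, with 1 dye, Cy3, on each array. RNA had been extracted with a column kit, checked on a Bioanalyzer and labelled with a 1-colour DNA labelling kit, per the labels' protocols. The groups were sons of unexposed parents, sons of mothers given 1 Gy of acute X-rays at 0.5 Gy per minute, and sons of fathers given the same dose, per the labels. The deposited array files hold 1 probe intensity per spot on a linear scale, and RMA is named as the method per the submitters' processing notes, with no version. From the values, the probe intensities of arrays on 1 slide shared their quantiles (medians from 422.2 to 422.4 on slide 1), while slides differed (medians from 353.0 on slide 3 to 540.5 on slide 5), so the normalization was made within slides. The values had not been summarised over probes. The deposited table of log2 values has 1 column per animal, per its header, and equalled the mean over arrays of the mean log2 of the probes of a sequence within 0.01 for 16 animals. For paternal 1 only 5.82% of its values did, and the best choice of 5 of the 6 arrays of this animal gave 10.5%, so that column was not used as given except in the alternative built on that table. Scale and centring of the table are known from this match, apart from that column, and column medians ran from 8.50 (paternal 5) to 9.08 (maternal 3).

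The arrays carry 135054 probes for 42575 target sequences, 35234 sequences with 3 and 7336 with 4 probes, and 2550 random-sequence control probes, which stayed out of all tests. Symbols came from the gene IDs or accessions on the arrays through a table of mouse genes: 38545 sequences were named by gene ID, 98 by accession, and 3932 kept their own identifier. The named sequences belong to 21698 genes, of which 10880 have more than 1 sequence. Each sequence was tested on its own, and in list tests a gene was represented by its brightest sequence. A named gene is given by the sequence with the smallest p or, in lists, by the brightest. Of the named genes with further sequences, 8 of 48, 9 of 48 and 2 of 38 had another of opposite sign in the 3 comparisons. No genome build is given in the sources used here, so no coordinates are printed. Signal over background limits what can be seen: 30151 sequences lay above the 95th percentile of the random probes.

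From the probe intensities, log2 values were averaged over the probes of a sequence. Slide differences were removed per sequence in a linear model with animal and slide, so that they were estimated within animals, and the arrays of an animal were averaged. Slides are numbered in the order of their identifiers. Slides 3 and 6 held 3 animals each, 1 per group, and are tied to the others through paternal 1 and paternal 5. All 17 animals entered 1 limma fit (version 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes with a mean trend). The 3 comparisons were sons of irradiated mothers against controls, sons of irradiated fathers against controls, and fathers' against mothers' sons, with two-sided tests adjusted by Benjamini-Hochberg over all sequences. Arrays of 1 animal are technical replicates and never counted as separate samples. Tables were handled with data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

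Before the data were examined, 37 gene lists were fixed, 18 of pathways and 19 of cell types and tissues, with 687 members of which 679 are on the arrays. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, and again with an estimated correlation and with fry. A list score is the mean over members of the log2 value minus the mean of that gene over all animals. Groups, comparisons, tests, the rule for named genes and 126 alternatives were fixed at the same time. By that rule a comparison names the 10 genes with the largest rise and the 10 with the largest fall among those past an adjusted p of 0.05. Where fewer pass, it adds those with the smallest unadjusted p until there are 20. It further names the 4 members with the smallest p of every shifted list and the 3 of the lists on the clock, p53 targets, DNA repair, DNA methylation and chromatin modifiers, imprinted genes and oxidative stress, together with the Y-linked genes. In all 145 genes other than the Y-linked ones were picked, a few of which are not reported here. The Y-linked genes were left out of the alternatives, decided after their small differences were seen to change sign, since only their levels are given.

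Exact two-sided permutation tests compared the mean squared deviation of animals from their group mean between groups. The likeness of the parental comparisons was set against 1000 simulated sets of unchanged groups sharing the 6 controls, and against 100 for shared sequences, of which those with slide-3 animals kept apart were added after the data were seen. Simulations that exchanged slide-3 animals only among themselves were preferred. Only this kind was tested on simulated data, so that test gives no ground for the choice. Alternatives covered the slide correction, a fit on arrays, weights, normalization, centring, the summary over probes, filters on dim sequences, the table of log2 values, the replicate number as a block, each slide alone, the fitted groups and prior, and leaving out each animal in turn. A block for the 3 slide-3 animals, their removal, and removal of 1 array of paternal 2 were added after the data were seen.

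The fit was tested on simulated data with 42575 sequences and the slide-3 structure. The changed sequences were drawn from those above the median intensity, so the shares called hold for brighter sequences only. All simulated slide-3 animals received the same added profile, while the real control 6, maternal 6 and paternal 5 differed among themselves (30.9, 45.6 and -57.1 on the second principal component). The shares may therefore be too high for the real groups. Of 50 changed sequences per size, it called 14%, 72%, 94% and 100% at 1.5-fold, 2-fold, 3-fold and 4-fold for sons of irradiated mothers against controls, with 1 unchanged sequence called. For sons of irradiated fathers it called 14%, 68%, 98% and 98%, with 0 unchanged. A list raised in simulated sons of irradiated mothers was found against controls, and 0 other lists were called in the 3 comparisons. Its fall in fathers' against mothers' sons was not scored. Without the slide-3 structure simulated it was found again, with 1 other list called in each comparison of fathers' sons. Noise was drawn independently per sequence, so these runs say nothing on lists whose members vary together. All 53 arrays were used, and no value column was left out. The array of paternal 6 carries another animal number in its file, and the source label of maternal 6 lacks a number, so both were assigned by their sample titles.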

Results

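Kidney RNA of 17 male BALB/c mice, an inbred laboratory strain, was measured on 53 single-colour oligonucleotide arrays. The animals were 6 control sons (18 arrays), 6 sons of mothers that had received acute X-rays (19 arrays) and 5 sons of fathers that had received them (16 arrays). The irradiated parents had received 1 Gy at 0.5 Gy per minute. Each animal was measured on 1 to 6 arrays spread over 6 slides, and its arrays were combined into 1 value, so n counts animals throughout. The litters and parents of the sons were not known here. Sons were therefore treated as independent, and an effect of litter was not tested. The arrays carried probes for 42575 target sequences, of which 30151 (70.8%) lay above the 95th percentile of the random-sequence control probes. Y-linked genes were expressed in all 17 animals, with means of 11.27 for Ddx3y, 11.06 for Eif2s3y, 10.70 for Uty and 9.87 for Kdm5d on the log2 scale, while Usp9y lay at 5.55. The number of arrays limits the precision of every value.

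The first question was how far values differed between arrays of the same animal and between animals. The median SD between arrays of 1 animal was 0.47 on the log2 scale after removal of slide differences, against 0.34 between animals of 1 group, whose values are means over arrays. Deviations from the mean of all arrays correlated with a median r of 0.217 over 69 pairs of arrays of the same animal, across sequences, which are not independent replicates. The median was -0.0251 over 375 pairs from different animals of 1 group and 0.00547 over 934 pairs from different groups. Control 6, maternal 6 and paternal 5, the 3 animals measured on slide 3, stood apart from the other 14. Their scores on the first principal component, which held 41.5% of the variance, were 115, 103 and 117, and those of the other animals ran from -45.9 to 15.4. Each group held 1 of these 3 animals, and the correction of slide 3 rests partly on paternal 5, which was also measured on slides 1 and 4.

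**Figure D1:**
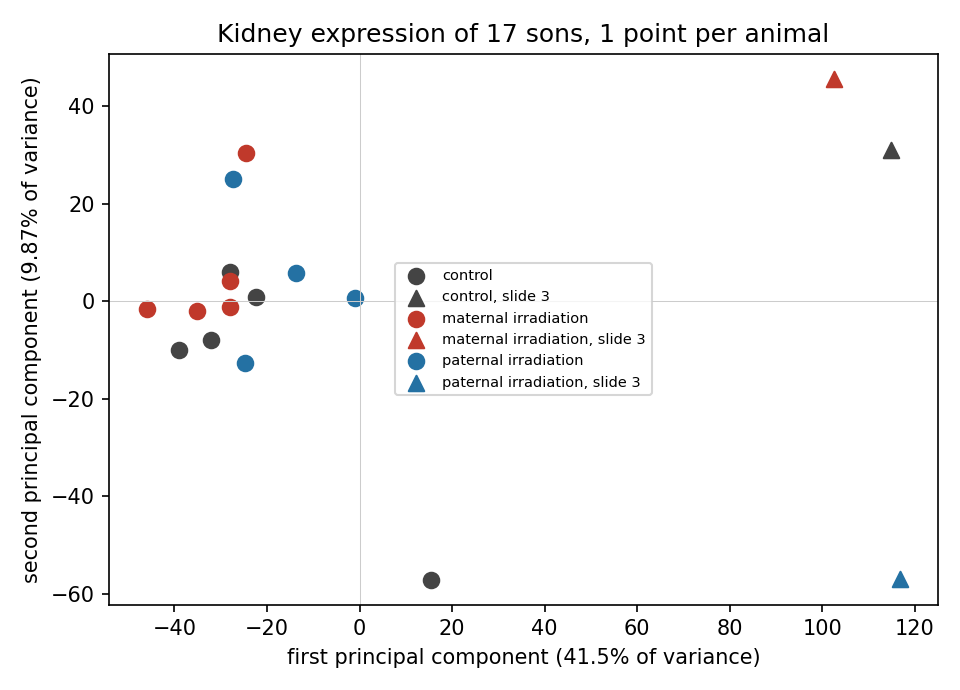
Scores of the 17 animals on the first and second principal components of log2 expression, in arbitrary units, coloured by group. The 3 animals measured on slide 3 score from 103 to 117 on the first component, and the other 14 lie between -45.9 and 15.4.

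Sons of irradiated mothers were compared with control sons to ask whether exposure of the mother is followed by different kidney expression in male offspring. Markers of smooth muscle, pericytes and fibroblasts were higher as a group, with all 10 measured markers higher by a median log2 difference of 0.41 (1.33-fold). The group score was 0.27 ± 0.15 against -0.13 ± 0.17 (SD, n = 6 and 6), and 5 of 6 sons of irradiated mothers lay above every control. Bcl6, a transcriptional repressor, lay at 13.05 ± 0.42 against 11.29 ± 0.77 on the log2 scale (SD, n = 6 and 6), 3.38-fold higher, with 6 of 6 sons above every control. Cish, an inhibitor of cytokine receptor signalling, was 4.16-fold lower at 10.03 ± 0.86 against 12.08 ± 0.72, and 5 of 6 sons lay below every control.

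Neither gene passed limma's test over all 42575 sequences, where the smallest adjusted p was 0.148, for Bcl6. No sequence had an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1053 sequences (732 higher and 321 lower), against a nominal 2129. The count was 650 without paternal 1, 1702 without maternal 6, 2187 with the slide-3 animals as a block and 2144 without them. The nominal count is not the level that chance gave here. At p under 0.01, with a nominal 426, the real groups gave 299. Regroupings of these animals with 1 slide-3 animal per group had a median of 68.5. The 20 genes with the smallest p are given with their log2 differences and SE and did not pass. The higher ones included Lama2 (0.89 ± 0.17), Egflam (0.80 ± 0.16), Adamts5 (0.68 ± 0.14), Loxl1 (0.84 ± 0.17), Adamtsl2 (0.66 ± 0.14), Srpx (0.94 ± 0.20) and Svep1 (0.65 ± 0.14). Lama2 encodes a laminin chain of basement membranes and Loxl1 an enzyme that cross-links elastin. Also higher were Gucy1a1 (0.66 ± 0.13), S1pr3 (0.60 ± 0.13), Tmem119 (0.73 ± 0.14), Tril (0.76 ± 0.16), Cyp1b1 (0.74 ± 0.16) and Cpxm1 (0.68 ± 0.15). Gucy1a1 encodes a subunit of soluble guanylate cyclase. Lower values were found for the insulin receptor substrate Irs2 (-0.997 ± 0.21), the activin receptor Acvr2b (-0.77 ± 0.14), and for Clec2h (-0.68 ± 0.12), Rhov (-0.72 ± 0.14) and Zfp655 (-0.68 ± 0.15). The differences of Bcl6 and Cish were 1.76 ± 0.28 and -2.06 ± 0.37.

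Within slides 1, 2, 4 and 5, which hold several animals of each group, Bcl6 was higher by 1.55 to 2.09, and the difference of Cish ran from -2.22 to -1.53. Without the 3 animals of slide 3, 12 sequences passed at an adjusted p under 0.05, 5 higher and 7 lower. Those that rose were Bcl6, Lama2, Tril, the stress-inducible Gadd45a and Ecm1, and those that fell were Cish with 3 sequences, Acvr2b, Irs2, Zfp655 and the clock repressor Ciart. Ecm1 was named after its values were seen. With these animals as a block, 8 sequences passed, and 6 passed without control 6. The count was 2 without control 7 (Bcl6 and Rhov), without paternal 1 (Bcl6 and Acvr2b) and without maternal 1 (both immunoglobulin kappa variable genes, picked out after their values were seen).

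**Figure D2:**
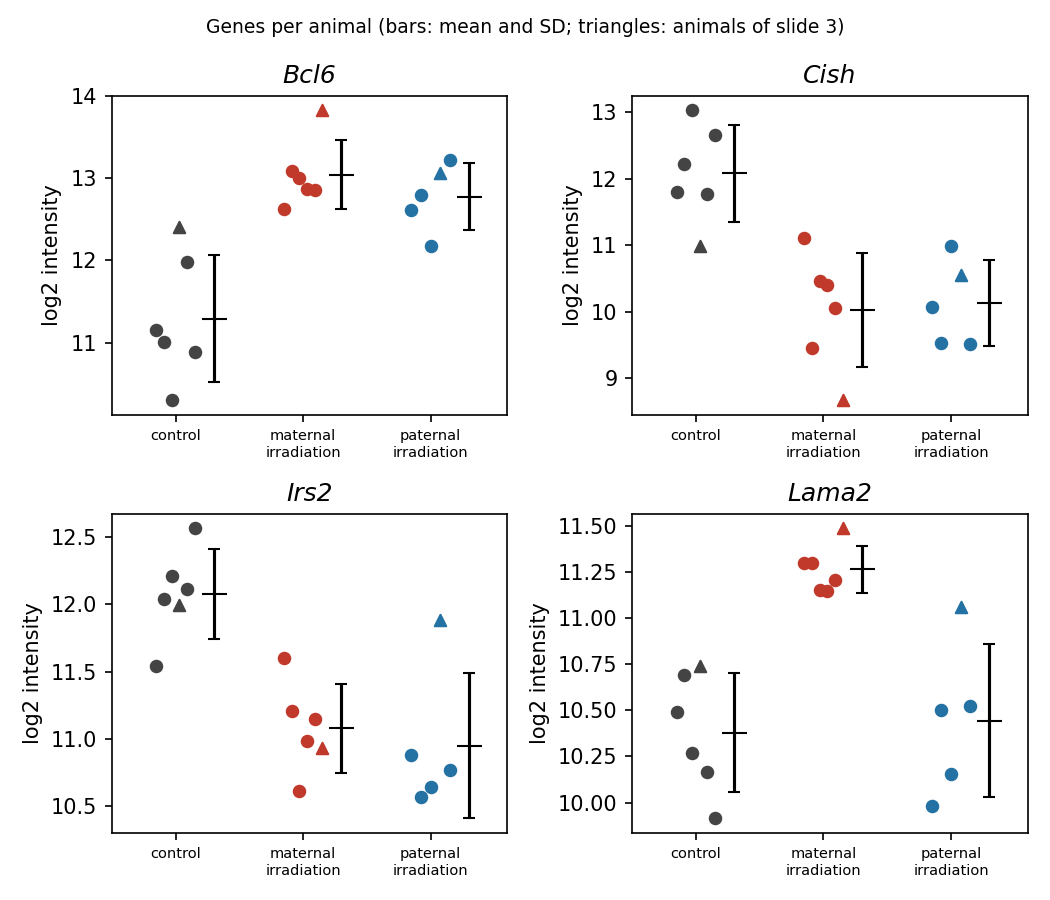
Log2 expression of Bcl6, Cish, Irs2 and Lama2 per animal in the 3 groups, with the mean and SD of each group; triangles are the 3 animals measured on slide 3. Bcl6 averages 13.05 in sons of irradiated mothers and 11.29 in control sons, and none of the 4 genes passed over all sequences.

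Of 37 gene lists, 13 were shifted in camera with a preset correlation of 0.01, 9 up and 4 down, and 0 members of any list passed over all genes. The stromal markers rose (adjusted p = 3.98e-16, and adjusted p = 0.0271 with an estimated correlation, the only call that held), and 6 of the 10 passed when adjusted over the list alone. Examples are the intermediate filament gene Des (0.65 ± 0.18), the growth factor receptor Pdgfra (0.52 ± 0.16), Tagln (0.41 ± 0.13) and Dcn (0.51 ± 0.17). On slides 1, 2, 4 and 5 the median ran from 0.31 to 0.40. Adipose tissue markers rose with 12 of 12 higher (median 0.45, adjusted p = 2.28e-09, and adjusted p = 0.174 with an estimated correlation). Examples are the adipokines Adipoq (0.74 ± 0.24), Lep (1.22 ± 0.48) and Retn (0.67 ± 0.22) and the regulator of fat cell differentiation Pparg (0.48 ± 0.17), and Adipoq, Retn and Pparg passed when adjusted over the list alone. All 12 adipose markers lay above the random probes in these kidneys. Kidney injury and inflammation genes rose, with 17 of 22 higher (median 0.16, adjusted p = 5.44e-05, and adjusted p = 0.0903 with an estimated correlation). Its leading members were fibronectin, Fn1 (0.59 ± 0.17), and Vcam1 (0.51 ± 0.14), Col3a1 (0.41 ± 0.14) and C3 (0.35 ± 0.15), and 2 passed when adjusted over the list alone. Of this list 4 members, and of the stromal list 3, belong to another list. Endothelial markers rose, with 10 of 10 higher (median 0.15, adjusted p = 0.000711, and adjusted p = 0.108 with an estimated correlation), led by Kdr (0.22 ± 0.099), Flt1 (0.19 ± 0.12), Ehd3 (0.21 ± 0.14) and Tek (0.15 ± 0.10).

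Cell cycle genes fell as a group, with 26 of 30 lower (median -0.18, adjusted p = 1.82e-06, and adjusted p = 0.174 with an estimated correlation). The mitotic genes Bub1b (-0.38 ± 0.16), Plk1 (-0.31 ± 0.16), Aurkb (-0.40 ± 0.20) and Cdca8 (-0.29 ± 0.16) led the list. Sterol synthesis genes rose, with 17 of 23 higher (median 0.061, adjusted p = 0.0121, and adjusted p = 0.108 with an estimated correlation), among them Fdps (0.18 ± 0.13) and Lss (0.19 ± 0.13). No member of the cell cycle, sterol or endothelial list passed when adjusted over the list alone. The shifts of these lists and of the stromal, adipose and kidney injury lists held in each of 17 refits that left out 1 animal, and without the slide-3 animals.

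The other 7 shifts each ended in at least 1 refit without 1 animal. Without the slide-3 animals those of DNA repair, B and plasma cells and skeletal muscle ended (adjusted p = 0.0871, 0.143 and 0.0619). Clock genes were shifted down, with 15 of 24 lower (median -0.064, adjusted p = 0.0208, and adjusted p = 0.174 with an estimated correlation). Adjusted over the list alone, the clock activator Arntl rose (1.01 ± 0.24) and the clock outputs Dbp (-0.81 ± 0.18) and Ciart (-0.64 ± 0.19) fell, and Npas2 did not pass (0.47 ± 0.21). Targets of p53 were shifted up, with 18 of 25 higher (median 0.031, adjusted p = 0.0380, and adjusted p = 0.323 with an estimated correlation). Only Gadd45a (0.81 ± 0.18) passed over that list alone, and Trp53inp1 (0.31 ± 0.15), Btg2 (0.34 ± 0.18) and Aen (0.16 ± 0.13) followed. DNA repair genes were shifted down, with 28 of 40 lower (median -0.060, adjusted p = 0.0219, and adjusted p = 0.726 with an estimated correlation), led by Mdc1 (-0.37 ± 0.14), Lig1 (-0.34 ± 0.18), Atm (-0.22 ± 0.14) and Brca2 (-0.22 ± 0.15). B and plasma cell markers were higher in 8 of 10 (median 0.16, adjusted p = 0.0254, and adjusted p = 0.174 with an estimated correlation). The antibody joining chain Jchain (1.42 ± 0.44) passed over the list alone, and Mzb1 (0.46 ± 0.23), Cd79a (0.39 ± 0.28) and Pou2af1 (0.29 ± 0.32) did not. Macrophage and dendritic cell markers were higher in 13 of 15 (median 0.16, adjusted p = 0.00231, and adjusted p = 0.174 with an estimated correlation), led by C1qa (0.24 ± 0.12), C1qc (0.26 ± 0.16), H2-Eb1 (0.16 ± 0.10) and Mrc1 (0.25 ± 0.17).

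Markers of tissues other than kidney moved as well. Skeletal muscle markers were higher in 8 of 10 (median 0.20, adjusted p = 0.0195, and adjusted p = 0.296 with an estimated correlation), led by Tnnt3 (0.40 ± 0.22), Ckm (0.62 ± 0.38), Acta1 (0.47 ± 0.31) and Tnni2 (0.21 ± 0.17), and 4 of the 10 lay above the random probes. Liver markers were lower in 9 of 11 (median -0.90, adjusted p = 0.00114, and adjusted p = 0.418 with an estimated correlation), led by the plasma protein genes Apoa2 (-1.01 ± 0.49), Apoa1 (-0.90 ± 0.50), Ahsg (-1.09 ± 0.62) and Fgb (-0.94 ± 0.62). Their score was -0.18 ± 0.73 against 0.44 ± 0.98 (SD, n = 6 and 6), a difference smaller than the spread between animals, and 8 of the 11 lay above the random probes. Shifts ended without control 2, control 8, maternal 3 or maternal 6 for the clock list (adjusted p up to 0.152). For p53 targets these were control 3, 6 and 7 and maternal 3, 4 and 5 (up to 0.255), and for DNA repair control 1, control 8 and maternal 6 (up to 0.274). For B cells they were control 7 and 8 and maternal 3, 4 and 6 (up to 0.318), and for macrophages maternal 6 (0.0938). For muscle they were control 1, 2 and 8 and maternal 3 and 6 (up to 0.255), and for liver control 7, control 8 and maternal 6 (up to 0.162). DNA methylation and chromatin modifiers, imprinted genes and oxidative stress genes were not shifted (adjusted p = 0.871, 0.212 and 0.673), with medians of -0.013, 0.058 and -0.016. Their leading members were Dnmt1 (0.28 ± 0.14), Tet3 (-0.22 ± 0.13) and Uhrf1 (-0.31 ± 0.18), then Magel2 (0.48 ± 0.21), Peg3 (0.24 ± 0.14) and Igf2r (-0.13 ± 0.098), and Mt1 (-0.19 ± 0.12), Gstm1 (0.13 ± 0.092) and Gsta4 (0.25 ± 0.19).

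Sons of irradiated fathers were compared with control sons to put the same question for exposure of the father. Bcl6 was 2.80-fold higher at 12.78 ± 0.41 against 11.29 ± 0.77, and Cish 3.86-fold lower at 10.13 ± 0.64 against 12.08 ± 0.72 (SD, n = 5 and 6), with 4 of 5 sons above and 5 of 5 below every control. Pnpla3, which encodes a lipid droplet protein, was 2.03-fold higher, and Irs2 was 2.19-fold lower. Stromal markers were not shifted (median -0.033, adjusted p = 0.552), and markers of podocytes were lower in 9 of 10 with a median of -0.13. The podocyte shift did not hold with an estimated correlation (adjusted p = 0.419) or without the slide-3 animals (adjusted p = 0.0705).

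No sequence had an adjusted p under 0.05 in limma, and the smallest was 0.354. At an unadjusted p under 0.05 there were 913 sequences (357 higher and 556 lower), against a nominal 2129. Without paternal 1 there were 495, with the slide-3 animals as a block 1827, and without these animals 2300. Among the 20 genes with the smallest p, none of which passed, the higher ones were Pnpla3 (1.02 ± 0.18), Bcl6 (1.49 ± 0.29), Lrp12 (0.85 ± 0.23), Alms1-ps2 (0.71 ± 0.13), Nat8f3 (0.69 ± 0.17) and Dnase1 (0.66 ± 0.13). Dnase1 encodes a secreted nuclease. The lower ones included Cish (-1.95 ± 0.39), Irs2 (-1.13 ± 0.22), Gadd45g (-0.91 ± 0.19), Pdk4 (-0.64 ± 0.17) and Acvr2b (-0.56 ± 0.14), of which Pdk4 inhibits pyruvate oxidation. Also lower were the proton pump subunit Atp6v1b1 (-0.71 ± 0.17), Clec2h (-0.70 ± 0.13), Lgals4 (-0.55 ± 0.12), Resf1 (-0.73 ± 0.19) and Dgkg (-0.64 ± 0.17) and Rhov (-0.58 ± 0.15), Sema4b (-0.57 ± 0.16), Zfp655 (-0.57 ± 0.13) and Txnrd3 (-0.39 ± 0.098). Within slides 1, 2, 4 and 5, Bcl6 was higher by 1.37 to 1.95, and the difference of Cish ran from -2.49 to -1.68. Without the 3 animals of slide 3, 8 sequences passed, 3 higher (Bcl6, Pnpla3 and Alms1-ps2) and 5 lower (Cish with 3 sequences, Irs2 and Vgll4, the last named after its values were seen). With these animals as a block, and again without control 6, Bcl6 alone passed, and without paternal 5 Irs2 alone did.

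Of the 37 lists, 7 were shifted, 2 up and 5 down, and 0 of these calls held with an estimated correlation. Liver markers fell in all 11 (median -0.91, adjusted p = 2.64e-05, and adjusted p = 0.452 with an estimated correlation), led by Alb (-1.40 ± 0.74), Ahsg (-1.13 ± 0.65), Apoa2 (-1.02 ± 0.51) and Apoa1 (-1.02 ± 0.52). The liver score was -0.31 ± 0.67 against 0.44 ± 0.98 (SD, n = 5 and 6), a difference smaller than the SD of the controls. The liver shift ended with the replicate number as a block. Over the alternatives other than single slides and left-out animals its median ran from -1.11 to -0.11. Adipose markers rose in 10 of 12 (median 0.29, adjusted p = 0.000372, and adjusted p = 0.547 with an estimated correlation), led by Lep (1.50 ± 0.50), Pparg (0.52 ± 0.18), Adipoq (0.48 ± 0.25) and Retn (0.43 ± 0.23), and Lep and Pparg passed when adjusted over the list alone. Podocyte and glomerular markers fell (adjusted p = 0.00867, and adjusted p = 0.419 with an estimated correlation). The slit diaphragm gene Nphs1 (-0.49 ± 0.15) passed over the list alone, and Magi2 (-0.20 ± 0.14) and Ptpro (-0.17 ± 0.12) did not. Loop of Henle markers were lower in all 9 (median -0.088, adjusted p = 0.0300, and adjusted p = 0.419 with an estimated correlation), led by Sostdc1 (-0.32 ± 0.18), Kcnj1 (-0.21 ± 0.12), Bst1 (-0.36 ± 0.21) and Slc12a1 (-0.12 ± 0.13). No member of the loop of Henle or liver list passed when adjusted over the list alone.

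Cell cycle genes were lower in 26 of 30 (median -0.11, adjusted p = 0.0104, and adjusted p = 0.709 with an estimated correlation), led by Cdca8 (-0.50 ± 0.17), Cenpa (-0.38 ± 0.20), Mcm2 (-0.20 ± 0.12) and Bub1b (-0.29 ± 0.17). Interferon response genes were lower in 22 of 26 (median -0.10, adjusted p = 0.0104, and adjusted p = 0.541 with an estimated correlation), led by Gbp3 (-0.37 ± 0.16), Psmb8 (-0.22 ± 0.14), Ddx58 (-0.20 ± 0.15) and Tap1 (-0.18 ± 0.14). Heat shock and unfolded protein genes were higher in 21 of 24 (median 0.077, adjusted p = 0.0104, and adjusted p = 0.419 with an estimated correlation). The chaperone genes Creld2 (0.42 ± 0.15), Calr (0.21 ± 0.13), Hsph1 (0.27 ± 0.18) and Hspa5 (0.15 ± 0.11) led that list. No member of these 3 lists passed when adjusted over the list alone. Without the slide-3 animals the median of the cell cycle list was 0.032, and the cell cycle, interferon, loop of Henle and podocyte shifts ended (adjusted p = 0.969, 0.353, 0.198 and 0.0705), while the other 3 held. The liver shift held in each refit without 1 animal, while that of cell cycle ended without control 1, control 6 or paternal 5 (adjusted p up to 0.602) and that of interferon genes without control 1, control 3 or paternal 5 (up to 0.532). The loop of Henle shift ended without control 1, control 6 or paternal 1, 5 or 6 (up to 0.192), heat shock without paternal 6 (0.184), podocytes without paternal 1 (0.172) and adipose without control 7 (0.0616).

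The lists on clock, p53, repair, chromatin, imprinting and oxidative stress were not shifted in sons of irradiated fathers. Clock genes had a median of 0.073 (adjusted p = 0.656), and of Npas2 (-0.79 ± 0.22), Nfil3 (-0.64 ± 0.23) and Per2 (0.55 ± 0.21) only Npas2 passed, as a fall, when adjusted over the list alone. Targets of p53 had a median of 0.014 (adjusted p = 0.638), led by Gadd45a (0.45 ± 0.19), Aen (0.27 ± 0.13) and Rrm2b (0.23 ± 0.19). DNA repair genes had a median of -0.041 (adjusted p = 0.123), led by Atm (-0.33 ± 0.14), Brca2 (-0.32 ± 0.16) and Mdc1 (-0.25 ± 0.15). Chromatin modifiers had a median of 0.00045 (adjusted p = 0.496), led by Dnmt3b (-0.48 ± 0.20), Tet3 (-0.28 ± 0.13) and Dnmt1 (0.25 ± 0.14), of which Dnmt3b encodes a DNA methyltransferase. Imprinted genes had a median of 0.074 (adjusted p = 0.143), led by Peg12 (0.37 ± 0.19), Plagl1 (-0.25 ± 0.15) and Nnat (0.50 ± 0.32). Oxidative stress genes had a median of 0.00056 (adjusted p = 0.978), led by Hmox1 (0.18 ± 0.13), Mt1 (-0.17 ± 0.13) and Gsta2 (-0.36 ± 0.28). The means of the chromatin and oxidative stress lists were -0.038 and -0.012, opposite in sign to their medians.

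**Figure D3:**
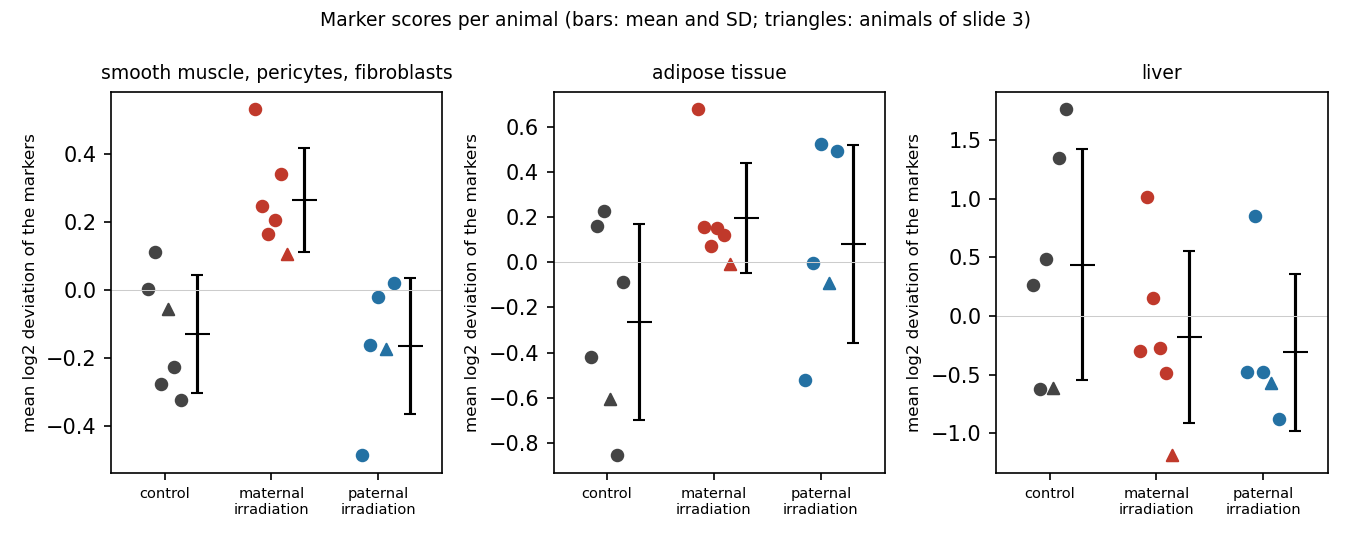
Mean score per animal of stromal, adipose and liver markers, in log2 relative to the mean of all animals, with the mean and SD of each group; triangles are the 3 animals measured on slide 3. The stromal score averages 0.27 in sons of irradiated mothers, -0.13 in control sons and -0.16 in sons of irradiated fathers, while liver scores spread widely in each group.

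Sons of irradiated fathers were set against sons of irradiated mothers, which also tests whether the effects of the 2 parental exposures differ. Stromal markers were lower in all 10 measured genes, by a median of -0.42, and their score was -0.16 ± 0.20 against 0.27 ± 0.15 (SD, n = 5 and 6), with 5 of 5 sons of irradiated fathers below every son of an irradiated mother. Clock genes moved in both directions. The activators Arntl and Npas2 were 2.67-fold and 2.39-fold lower, and the repressor Ciart and the output gene Dbp 2.09-fold and 1.91-fold higher. Lama2 was 1.77-fold lower, at 10.44 ± 0.41 against 11.27 ± 0.13.

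No sequence had an adjusted p under 0.05 in limma, and the smallest was 0.116, for the pseudogene Alms1-ps2 (0.85 ± 0.13). At an unadjusted p under 0.05 there were 1380 sequences (478 higher and 902 lower), against a nominal 2129. Without paternal 1 there were 646, and without maternal 6 2546, more than the nominal count. With the slide-3 animals as a block there were 2888, and without these animals 3028, again more. Among the 20 genes with the smallest p, clock genes were Arntl (-1.42 ± 0.25, and -1.31 ± 0.26 for another of its sequences), Npas2 (-1.26 ± 0.22), Ciart (1.07 ± 0.20), Dbp (0.93 ± 0.19) and Usp2 (0.53 ± 0.12). Lower ones were Lama2 (-0.82 ± 0.18), Fn1 (-0.77 ± 0.18), Svep1 (-0.70 ± 0.15), Adamts5 (-0.62 ± 0.15), Ccn2 (-0.64 ± 0.14), Gucy1a1 (-0.78 ± 0.14), S1pr3 (-0.59 ± 0.13) and Tril (-0.79 ± 0.17). The other genes were Polr3e (-1.07 ± 0.20), Nat8f3 (0.80 ± 0.17), Dnase1 (0.60 ± 0.13), Cpm (-0.73 ± 0.17), Cpxm1 (-0.68 ± 0.16) and Psmb8 (-0.59 ± 0.14). On the 4 slides with several animals of each group, the difference of Npas2 ran from -1.59 to -1.16 and that of Lama2 from -1.13 to -0.67, while Dbp turned to -0.10 on slide 2. The second Lama2 sequence differed in sign (0.15). Without the 3 animals of slide 3, 22 sequences passed, 6 higher and 16 lower, among them 3 sequences of Arntl, 2 of Npas2, and Ciart, Per2, Lama2, Fn1 and Gucy1a1. With these animals as a block, Arntl, Npas2, Lama2 and Alms1-ps2 passed, and without maternal 6 Arntl, Npas2 and Alms1-ps2 did.

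Of the 37 lists, 6 were shifted, 1 up and 5 down. Stromal markers fell (adjusted p = 2.06e-15, and adjusted p = 0.0211 with an estimated correlation), and all 10 passed when adjusted over the list alone, among them Tagln (-0.50 ± 0.13), Dcn (-0.57 ± 0.18), Pdgfra (-0.49 ± 0.16) and Myh11 (-0.35 ± 0.13). Endothelial markers fell in all 10 (median -0.22, adjusted p = 7.83e-07, and adjusted p = 0.0211 with an estimated correlation), led by Pecam1 (-0.40 ± 0.15), Tek (-0.29 ± 0.11), Emcn (-0.30 ± 0.12) and Kdr (-0.21 ± 0.10), none of which passed over the list alone. Macrophage and dendritic cell markers were lower in 14 of 15 (median -0.23, adjusted p = 3.81e-05, and adjusted p = 0.0938 with an estimated correlation), led by Mrc1 (-0.46 ± 0.18), Cd74 (-0.38 ± 0.17), H2-Aa (-0.35 ± 0.20) and H2-Eb1 (-0.26 ± 0.11), with none passing over the list alone. Kidney injury and inflammation genes were lower in 13 of 22 (median -0.22, adjusted p = 0.000813, and adjusted p = 0.119 with an estimated correlation). Fn1 and Vcam1 (-0.49 ± 0.15), Col3a1 (-0.42 ± 0.15) and C3 (-0.37 ± 0.16) led it, and 2 passed when adjusted over the list alone. Interferon response genes were lower in 21 of 26 (median -0.15, adjusted p = 0.000588, and adjusted p = 0.215 with an estimated correlation). The immunoproteasome gene Psmb8 passed over that list alone, and Gbp3 (-0.43 ± 0.16), Psmb9 (-0.30 ± 0.15) and Gbp2 (-0.22 ± 0.14) did not.

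Clock genes were shifted up, with 17 of 24 higher (median 0.14, adjusted p = 0.0153, and adjusted p = 0.211 with an estimated correlation). Adjusted over the list alone 8 passed: Per2, Dbp, Ciart, Bhlhe40 and Wee1 rose, and Arntl, Npas2 and Nfil3 fell. The stromal, endothelial, macrophage and kidney injury shifts held in each refit without 1 animal. The clock shift ended without maternal 6, paternal 2 or paternal 6 (adjusted p up to 0.157) and the interferon shift without paternal 5 (0.120) and without the slide-3 animals (0.0576). Adipose and liver markers were not shifted between these groups (adjusted p = 0.223 and 0.324). Lists of p53 targets, DNA repair, chromatin modifiers, imprinted genes and oxidative stress were not shifted either (adjusted p = 0.239, 0.648, 0.539, 0.814 and 0.617), with medians of -0.041, 0.016, -0.012, -0.0058 and 0.0029. Their leading members were Btg2 (-0.47 ± 0.19), Gadd45a (-0.36 ± 0.19) and Rrm2b (0.34 ± 0.19), then Atr (0.32 ± 0.21), Mutyh (-0.30 ± 0.21) and Brca1 (-0.32 ± 0.26), then Dnmt3b (-0.56 ± 0.20), Kdm1a (-0.32 ± 0.13) and Dnmt3a (-0.23 ± 0.17), then Peg3 (-0.36 ± 0.15), Slc38a4 (0.53 ± 0.25) and Peg12 (0.35 ± 0.19), and Keap1 (0.22 ± 0.11), Hmox1 (0.20 ± 0.13) and Gsta4 (-0.25 ± 0.20). The mean of the imprinted list, 0.010, was opposite in sign to its median.

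The 2 parental comparisons were then set against each other. Bcl6, Cish, Irs2, Acvr2b, Clec2h, Rhov and Zfp655 were among the 20 genes with the smallest p in both, each in the same direction. At an unadjusted p under 0.01, 10 sequences were higher in both and 19 were lower in both, where independent lists would share 0.287 and 0.149. Both comparisons use the same 6 controls. Unchanged groups simulated against shared controls, with slide-3 animals exchanged only among themselves, shared a mean of 4.06 and 4.40 (up to 38 and 43), with 11 and 4 of 100 simulations as large. With all animals exchanged freely, so that slide-3 animals fell unevenly in many simulations, 26 and 20 of 100 were as large (up to 1049 and 2229). The log2 differences correlated with r = 0.331 across sequences (jackknife SE 0.337), which are not independent replicates, and 62.1% had the same sign. Simulated unchanged groups gave a mean r of 0.467 when slide-3 animals were exchanged only among themselves, 820 of 1000 with an r as large as the observed one, and the covariance was 0.0135 against a simulated mean of 0.0196. With the controls split so that each comparison used 3 of them, r averaged -0.206 over 20 splits, and -0.0335 without the slide-3 animals.

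The last comparison asked whether sons of irradiated parents differed more among themselves than control sons. The mean squared deviation of an animal from its group mean, over all sequences, was in a ratio of 0.919 for sons of irradiated mothers to controls (two-sided exact permutation p = 0.719, n = 6 and 6). The ratio was 1.15 for sons of irradiated fathers to controls (exact permutation p = 0.639, n = 5 and 6) and 1.25 for sons of irradiated fathers to sons of irradiated mothers (exact permutation p = 0.504). These 3 ratios did not differ from 1 beyond chance. The 3 slide-3 animals had the largest deviations of their groups, at 0.443 for control 6, 0.440 for maternal 6 and 0.469 for paternal 5, and those of the other animals ran from 0.0679 to 0.182.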

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

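The tests of slide 3 itself, of short transcripts and of clock phase, those over splits that put 1 slide-3 animal in each group, and those of a list against all lists were chosen after the result was seen.

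An animal stood apart from the others of its group in 42 of 471 groups of values tested, where chance would give 24, and in 27 of the 42 it was the animal measured on slide 3. Values in brackets are log2 expression of genes or log2 list scores. Paternal 5 stood apart from its group in Irs2 (11.89), Lig1 (9.58), Alms1-ps2 (10.44), Rrm2b (10.07), Mcm2 (10.03) and Usp2 (13.10), and in the list score of p53 targets (-0.24), DNA repair (-0.38), sterol synthesis (-0.18) and interferon response (-0.39). Control 6 was the outlying animal for Gadd45a (13.06), Fdps (11.99), Acta1 (9.04), Rrm2b (9.54), Sostdc1 (13.89), Nphs1 (11.24) and Atr (8.03). Maternal 6 lay outside its group for Lep (5.84), Pdk4 (10.21), Per2 (11.46), Kcnj1 (12.42), Dnmt3a (12.98) and Cd74 (13.02), and in the list score of endothelium (-0.12). Maternal 1 stood apart from its group in Adipoq (11.71), Txnrd3 (12.09) and Gsta2 (12.84), and in the list score of adipose tissue (0.68). Paternal 2 was the outlying animal for Ckm (7.29), Atp6v1b1 (9.45) and Alb (11.84), and in the list score of liver (0.85). Paternal 1 lay outside its group for Svep1 (11.00) and C3 (10.65). Control 7 stood apart from its group in Hspa5 (14.23) and H2-Aa (10.88). Paternal 3 was the outlying animal for H2-Aa (10.61). Maternal 2 lay outside its group for Cdca8 (8.37). Paternal 6 stood apart from its group in Ptpro (10.56). The mean squared deviation over all sequences was 0.443 for control 6, 0.440 for maternal 6 and 0.469 for paternal 5. An array of paternal 2 on slide 1 had a slope of log2 intensity along transcripts of 0.791 per kb, where the other arrays of that slide lay between -0.178 and 0.0649. On slide 3 an array of maternal 6 and an array of control 6 were steeper, at 1.351 and 1.01. All were kept. Without the array of paternal 2, 0 sequences passed in each comparison, and the other 2 were left out only together with their animals.

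Fathers' and mothers' sons differed in 6 lists, in the test of the difference itself. The median log2 differences were -0.42 for stromal, -0.22 for endothelial and -0.23 for macrophage markers, -0.22 for kidney injury, -0.15 for interferon response and 0.14 for clock genes. With an estimated correlation only the stromal and endothelial shifts held (adjusted p = 0.0211 and 0.0211), while those of macrophages, kidney injury, interferon and clock genes did not (0.0938, 0.119, 0.215 and 0.211).

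The 3 animals of slide 3, 1 in each group, lay far from the other 14 on the first principal component. Slide 3 itself, with a correction that rests partly on paternal 5, stays open for control 6 and maternal 6. Their difference from paternal 1 on slide 6 correlated at only -0.0919 and -0.103 with the arrays of paternal 5 on slides 1 and 4. These correlations lay inside the range of the other arrays there. The correlation of 0.683 and 0.683 with the corrected values of control 6 and maternal 6 is set aside as partly built in by that correction. For paternal 5 slide 3 is argued against as the whole cause, since its arrays off that slide stood apart too. The 95th percentiles of their random probes were 5.46 and 6.08 on slides 1 and 4. Those of the other arrays there were at least 7.05 and 7.67. Loss of signal towards 1 end of the transcripts is argued against for paternal 5. For control 6 and maternal 6 this holds only as far as paternal 1 is a fair reference on slide 6. The slopes of paternal 5 on slides 1 and 4 (mean -0.0713 per kb) lay inside the range of the others there. Those of control 6 and maternal 6 on slide 6 (-0.00425 to 0.0795) overlapped those of paternal 1. All comparisons on slide 6 rest on the 2 arrays of paternal 1 there. After slide removal their mean correlation with the other arrays of that animal was only -0.042 and -0.150, so paternal 1 is an uncertain reference. On slide 3 control 6 and maternal 6 had arrays of either sign (-0.730 to 1.351 over all 6 arrays). Enrichment of short transcripts stays open for paternal 5, with correlations of log2 deviation with length of -0.259 and -0.270 below every other array of slides 1 and 4. It stays open for maternal 6 too, with -0.0822 in its 1 array on slide 6. For control 6, whose 2 arrays there (0.0178 and 0.0657) lay above paternal 1, it is argued against only as far as that reference holds. Each group holds 1 such animal, so no biological explanation was tested.

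Stromal markers were higher in sons of irradiated mothers than in control sons by 0.39 in score (exact permutation p = 0.00433, n = 6 and 6). More fat in the samples is argued against as the whole cause, since a difference of 0.33 was left with the adipose score as a covariate (83.1%, exact permutation p = 0.00216, the smallest these animals can give). A different share of medulla, as far as these markers show it, is argued against as the whole cause. The medullary score itself differed by only -0.016 (exact permutation p = 0.716). With it as a covariate 0.42 was left (105%, exact permutation p = 0.00216), which decides nothing, since a score that hardly differs between the groups can take little away. More renal capsule was not tested and stays open, as does exposure of the mother.

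Clock genes differed between fathers' and mothers' sons, with the arm of Arntl lower by a mean difference of -0.61 and the arm of Dbp higher by 0.45. The difference of the arms was -1.06 (exact permutation p = 0.00433, adjusted 0.0130 over 3 comparisons, n = 5 and 6), and -1.11 without the slide-3 animals (exact permutation p = 0.00794). It was 0.62 for mothers' sons against controls (exact permutation p = 0.0152) and -0.44 for fathers' sons against controls (exact permutation p = 0.0390), the last falling to -0.28 without the slide-3 animals (exact permutation p = 0.127). Opposite arms are what another time of day or clock phase at sampling would give, and this may be the explanation, but no time of sampling is given in the labels and exposure of the parents stays open too.

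Regrouping the animals showed which counts chance can give, with 100 splits of the animals of each pair of groups, the real one included. For sequences at an adjusted p under 0.05 this decides nothing, as with 0 in the real splits all 100 of 100 were bound to be as large in each comparison (highest other 7, 23 and 1). At an unadjusted p under 0.01, 33, 60 and 36 splits gave as many as the real 299, 165 and 327. Others reached 1635, 1894 and 1492, several times the real counts, when slide-3 animals fell unevenly, which points to that structure of the samples. Over all splits chance cannot be excluded for these counts. Among splits with 1 slide-3 animal per group, 1 of 60, 19 of 53 and 5 of 50 were as large, with 257, 436 and 740 as the highest of the others. For mothers' sons against controls that 1 was the real split, so among these splits chance is argued against there, but not in the other comparisons. With the slide-3 animals as a block the real counts of 8, 1 and 4 were met by 5, 6 and 3 splits (highest other 52, 25 and 12), so chance cannot be excluded for the first and second comparison. For fathers' against mothers' sons 3 of the 50 splits with 1 slide-3 animal per group gave as many, so chance cannot be excluded there either.

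Shifted lists were as many as the real 13, 7 and 6 in 1, 8 and 32 of the 100 splits (highest other 11, 8 and 12). Chance is argued against for mothers' sons against controls alone, where that 1 split was the real one. This is the smallest share that 100 splits can give, and the tests over splits were not adjusted for their number. Stromal and clock genes were chosen for their shifts, so that their own p in other splits does not decide, although it was as small in only 1 split for stromal markers in mothers' sons against controls (1.07e-17, smallest other 7.04e-15). The like counts in fathers' against mothers' sons were 1 for stromal markers (5.55e-17, smallest other 8.53e-10) and 4 for clock genes (0.00248, smallest other 0.000109).

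Set against the smallest p of all lists in each split, the stromal shift between fathers' and mothers' sons was matched in 1 of 100 splits, the real one (smallest other 3.40e-11), so chance is argued against. That of mothers' sons against controls was matched in 4 of 100 (smallest other 3.96e-20). Those 4 lie among the 60 with 1 slide-3 animal per group, as the real groups had, so chance cannot be excluded for it. The clock shift was matched in 93 of 100 splits (smallest other 3.40e-11), so chance cannot be excluded for it as a list. Camera tests for a shift of a list in 1 direction, and the arms of the clock moved oppositely, so this does not decide on the arms.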

How the results depend on the processing

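The block and the removal of the slide-3 animals and of the steep array were tests chosen after the data were seen. Over the alternatives, 7556 of 7798 values of named genes kept their direction and side of the threshold, 170 passed it and 72 changed sign. No named gene passed in the main fit, so none could lose a pass, and keeping the side means that the gene still did not pass. Of 1011 list values 845 stayed, 156 lost the shift and 10 changed direction in the test, and the correlation of the parental comparisons stayed between 0.179 and 0.527. The cause of the movements below was not tested, except that the fit on arrays counts arrays of 1 animal nearly as separate samples (correlation 0.0445), and single slides hold fewer animals.

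Counts follow in the order of mothers' sons against controls, fathers' sons against controls, and fathers' against mothers' sons. Sequences at an adjusted p under 0.05, 0 in each, were 3, 1 and 0 without slide correction (Acvr2b, Gadd45a and Bcl6, then Bcl6) and 3, 1 and 0 from the authors' table, for the same genes. They were 114, 21 and 233 in the fit on arrays, 41, 27 and 107 with quality weights, 0, 0 and 1 with median centring (Alms1-ps2), 8, 1 and 4 with the slide-3 block and 12, 8 and 22 without these animals. Leaving out 1 animal gave 0 to 6, 0 to 1 and 0 to 3. At an unadjusted p under 0.01 there were 299, 165 and 327, and 182, 70 and 114 without paternal 1, 213 in the last without maternal 1 and 569 without maternal 6. The counts at that p rose to 690, 362 and 879 with the slide-3 block and to 658, 492 and 822 without these animals. Shifted lists, 13, 7 and 6, were 1, 0 and 2 with an estimated correlation and 0, 0 and 2 with fry, and leaving out 1 animal gave 8 to 17 (8 without control 8), 4 to 9 (4 without control 1) and 6 to 10 (10 without maternal 6 or paternal 3). Weights by arrays gave 7, 11 and 7, quality weights 8, 7 and 14, the fit on arrays 11, 12 and 8, the brighter part of the sequences 10, 4 and 10 and sequences above the random probes 12, 4 and 9. The authors' table gave 12, 9 and 10 and removal of the slide-3 animals 10, 5 and 11. Slides 1, 2, 4 and 5 alone gave 7, 10 and 11, then 5, 0 and 6, then 7, 4 and 3, and 2, 6 and 6.

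Ratios of spread, 0.919, 1.15 and 1.25, ran without 1 animal from 0.518 to 1.64, 0.656 to 2.17 and 0.648 to 2.24. They crossed 1 without control 6 (1.64) and without maternal 1, 2 or 4 or paternal 5 (1.01 to 1.03) in the first, and without paternal 1 (0.8294 and 0.948) or paternal 5 (0.656 and 0.648) in the others. The brighter part of the sequences gave 0.943 and 0.985 in those, and 1 array per animal 0.596 for fathers' sons against controls. No exact permutation p was under 0.05.

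Animals of different groups share a replicate number, and some of these also their slides. Same-numbered animals deviated together with r from -0.312 to 0.821 over 13 pairs, 6 of them over 0.1, and 2 of 8, 3 of 8 and 0 of 10 animals correlated best with their own number. With the replicate block 1, 0 and 0 sequences passed (Bcl6) and 6, 7 and 6 lists were shifted, and the block turned Cd79a to -0.071 and the liver list to 0.037 for mothers' sons against controls.

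The log2 differences that changed sign, none of which passed a test there, were these. With the median over probes, the sign turned for fathers' sons against controls, Hspa5 (-0.031) and Slc12a1 (0.0073). On slide 1 alone, the sign turned for mothers' sons against controls, Mdc1 (0.068) and Lss (-0.035). It turned for fathers' sons against controls, Rrm2b (-0.037), Plagl1 (0.083), Gsta2 (0.028), Psmb8 (0.083), Calr (-0.14), Sostdc1 (0.030), Bst1 (0.078) and the loop of Henle list (0.030). It also turned for fathers' against mothers' sons, Atr (-0.30), Keap1 (-0.10), Psmb9 (0.087), Gbp2 (0.17) and H2-Aa (0.18). On slide 2 alone, the sign turned for mothers' sons against controls, Tet3 (0.10), Cd79a (-0.072), Pou2af1 (-0.024), C1qa (-0.21) and the B cell list (-0.048). It turned for fathers' sons against controls, Brca2 (0.010), Mdc1 (0.18), Tet3 (0.042), Hmox1 (-0.034), Cenpa (0.077), Mcm2 (0.27), Gbp3 (0.066), Psmb8 (0.44), Ddx58 (0.0098), Ptpro (0.39) and the interferon response list (0.12). It also turned for fathers' against mothers' sons, Dbp (-0.10), Dnmt3b (0.032) and Peg12 (-0.019). On slide 4 alone, the sign turned for mothers' sons against controls, Aen (-0.15), Dnmt1 (-0.0049), Gstm1 (-0.11), C1qa (-0.026), C1qc (-0.20), Mrc1 (-0.16), Ckm (-0.063), Acta1 (-0.14) and the skeletal muscle list (-0.0034). It turned for fathers' sons against controls, Rrm2b (-0.021), Dnmt1 (-0.11), Tap1 (0.17), Hspa5 (-0.037), Slc12a1 (0.089), Pparg (-0.068), Adipoq (-0.068), the loop of Henle list (0.089) and the adipose tissue list (-0.073). It also turned for fathers' against mothers' sons, Kdm1a (0.022), Peg3 (0.015), Cd74 (0.027) and the macrophage list (-0.050). On slide 5 alone, the sign turned for mothers' sons against controls, Atm (0.21), Uhrf1 (0.10), Mt1 (0.056), Bub1b (0.036), Flt1 (-0.0061), Mzb1 (-0.12), Tnnt3 (-0.43), Ckm (-0.027), Tnni2 (-0.084), Apoa1 (0.025), Fgb (0.57), the skeletal muscle list (-0.10) and the liver list (0.028). It turned for fathers' sons against controls, Atm (0.22), Peg12 (-0.19), Nnat (-0.033), Mt1 (0.027), Bub1b (0.087), Slc12a1 (0.011) and Retn (-0.075). It also turned for fathers' against mothers' sons, Btg2 (0.012) and Mutyh (0.70). For the macrophage list the direction of the test turned and the median did not. The median alone turned for p53 targets in mothers' sons against controls and adipose tissue in fathers' sons against controls with quality weights (-0.0031 and -0.068), and for B cells in the former with the replicate block (-0.0062). It did so for the cell cycle list of fathers' sons against controls without the slide-3 animals (0.032), and on slide 2 for their podocyte list (0.10) and the interferon list of fathers' against mothers' sons (0.090).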

Other observations

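Both tests below were chosen after the differences of Cish and Bcl6 were seen, and their own values were not known then, except that levels of the clock genes per animal had been seen. The STAT5 targets Socs2 and Igf1 had been seen as well and were left out.

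Segments of the nephron other than those described were not shifted in camera. For sons of irradiated mothers against controls the median log2 differences were -0.027 (adjusted p = 0.490) for proximal tubule, -0.055 (adjusted p = 0.673) for distal convoluted tubule, -0.089 (adjusted p = 0.673) for collecting duct principal cells and -0.038 (adjusted p = 0.285) for intercalated cells. For sons of irradiated fathers against controls they were 0.031 (adjusted p = 0.656), 0.0026 (adjusted p = 0.916), -0.033 (adjusted p = 0.870) and -0.070 (adjusted p = 0.122) in the same order. Genes of oxidative phosphorylation differed by -0.014 (adjusted p = 0.391) and 0.051 (adjusted p = 0.259), and cytosolic ribosomal protein genes by 0.017 (adjusted p = 0.596) and 0.0099 (adjusted p = 0.245). T and natural killer cell markers were higher in 10 of 12 in sons of irradiated mothers, by 0.086 (adjusted p = 0.0572), without passing. Albumin, a liver gene, varied between single animals of each group, from 9.00 to 13.34 in controls, from 8.00 to 12.30 in mothers' sons and from 9.07 to 11.84 in fathers' sons on the log2 scale.

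Cish was lower and Bcl6 higher in sons of irradiated fathers and mothers alike. Cish is induced, and Bcl6 repressed, by STAT5 downstream of growth hormone, so a hypothesis is that growth hormone and STAT5 signalling was lower. Then other STAT5 targets should be lower too, but Socs1, Socs3, Pim1, Pim3, Ccnd2 and Bcl2l1 had a median log2 difference of 0.099 in mothers' sons (exact permutation p = 0.297) and -0.073 in fathers' sons (exact permutation p = 0.589), neither beyond its spread, which decides nothing. The targets seen before differed by -0.27 ± 0.18 for Socs2 and 0.26 ± 0.17 for Igf1 in mothers' sons, and by -0.59 ± 0.19 and 0.067 ± 0.18 in fathers' sons (SE), so lower STAT5 signalling stays open. A second hypothesis, a shift of clock phase, was tested with the difference of the clock arms as a covariate, and 91.5% to 107% of the differences in Cish and Bcl6 was left, which argues against it as the whole cause. Neither gene passed over all sequences in the fit with slide correction and no block, while Bcl6 passed in both comparisons without that correction and with the slide-3 animals as a block. Both comparisons use the same controls, so a chance difference of the controls stays open.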
